A study of Mus musculus with 4 samples.

How the data were processed

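The series measured RNA in mouse cochleovestibular ganglia (CVG), the clusters of young sensory neurons beside the inner ear, at embryonic day 11.5. There were 4 libraries, 1 for each genotype label: control, Isl1CKO, Pou4f1KO and DKO. The label Isl1CKO was read as a conditional knockout of Isl1, Pou4f1KO as a knockout of Pou4f1 and DKO as a knockout of both genes. Ganglia were dissected and frozen, RNA was extracted with Trizol, and strand-specific libraries were made with an Illumina-type directional kit, per the labels' protocols. Whether a library held 1 embryo or several is not given in the sources used here.

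Each library came as 1 table of gene abundances with a gene symbol, chromosome, strand, start and end for each gene. Per the submitters' processing notes, the tools were Trimmomatic, FastQC, HISAT2, SAMtools and StringTie, and the genome build was mm10. The notes used here give no order, version or settings for these tools. The gene annotation is not given in the sources used here. The first unit was TPM, a transcript abundance scaled for gene length and library total, which the authors computed and which summed to the same total in each library, per the file headers and the values. The deposited tables also gave FPKM, fragments scaled for gene length and depth, which differed from TPM by 1 constant factor in each library. The third deposited value was coverage, the mean read depth over the bases of a gene, which was not scaled between libraries per the file headers.

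The tables gave no read counts, so the depth was read from the ratio of coverage to FPKM. This ratio was the same, within a tolerance of 0.001, for 55.9% to 56.3% of the genes of a library, and it corresponds to the gigabases of aligned sequence. TPM was used as deposited, with rows that share a symbol summed, which gave 25239 symbols. A gene entered a comparison if it reached 1 TPM in at least 1 of the 4 libraries, which left 15049 genes. The symbols were matched to GENCODE release M21 of the mouse annotation for gene type and exon numbers: 24366 symbols (96.5%) were found, and 24197 of these overlapped the annotated gene on the same strand. Of the compared genes, 13613 were protein coding there.

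The difference between 2 libraries was the log2 ratio of (TPM + 1), a scale that understates differences of weakly expressed genes. A gene was counted as higher or lower if this ratio was at least 1 in size, which is 2-fold. With 1 library per genotype there is no estimate of the spread between replicates, so no p-value was computed and each count describes these libraries. A count test did not suit TPM values and was not run.

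The comparisons were each mutant library against the control library, the library labelled DKO against each single mutant, and the departure from additivity. The departure is the log2 ratio of the library labelled DKO to control minus the sum of the log2 ratios of both single mutants, and it has no residual degrees of freedom. The difference tied to each gene's label was also compared in both backgrounds, which uses 2 pairs of libraries with no library in common. Both single mutants share the control library, so the number of genes that differ in both was set against 100 simulated pairs in which no gene differed but the control was shared.

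The design, the comparisons, the processing alternatives, the rule for naming genes and 26 gene lists were fixed before the data were examined. The rule named Isl1 and Pou4f1; the 12 genes with the largest ratios in each direction for each mutant against control; 6 in each direction for the library labelled DKO against each single mutant; and 8 in each direction for the departure. Such a gene needed 5 TPM in the higher library and an ordinary gene symbol. The rule also leaves out symbols given to more than 1 gene identifier. Because symbols serve as identifiers here, this was taken as the 260 symbols that stand on more than 1 row. Up to 4 members were named per list in each comparison, and other genes are said to have been chosen after their values were seen.

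Besides the targeted genes, the lists held otic neurogenesis factors, pan-neuronal genes, neurotrophic factors and receptors, axon guidance genes, ion channels and transmitter machinery, neuropeptides and dense-core vesicle genes, somatosensory ganglion genes, Notch signalling genes, p53 target genes, apoptosis regulators, proliferation genes, sex-linked genes, immediate-early and stress genes, and glycolysis and hypoxia genes. Lists of markers of other cells that a dissected ganglion could hold covered neural tube and hindbrain factors, visceral and motor neuron factors, Hox genes, glia and neural crest, otic epithelium, surface ectoderm and epithelium, mesenchyme, cartilage and muscle, endothelium, erythroid cells and macrophages. Some genes stand in more than 1 list. For each list the median log2 ratio of its measured members was placed among the medians of 10000 random lists of the same size, drawn from the same 20 bins of mean expression. The resulting percentile describes these libraries and is not a p-value.

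The calculation was tested on simulated data for 1 library against 1 library, with the spread taken from the Isl1CKO and control libraries. For that pair the spread is an upper bound because it includes true differences. Among 15049 genes, 200 with a mean expression above that of 5 TPM were given known differences on the log2 scale of (TPM + 1). Weaker genes were not among these 200, so the recovery of their differences was not tested. The size rule found 100% of the changed genes with a log2 difference of 2 and 98% of those with 1.5, in either direction. It also took in 1.19% of the 14849 genes left unchanged. That share restates the 1.20% of genes past 2-fold between the Isl1CKO and control libraries, so it is no rate of false calls. All 20 simulated lists shifted by 1 log2 unit stood above percentile 97.5, and 0 of 20 unshifted lists fell outside the range from 2.5 to 97.5. The simulated genes varied independently, so this does not check lists whose members vary together, nor smaller shifts.

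The settings varied were pseudocounts of 0.1 and 5, no filter on low values, a filter of 5 TPM, FPKM in place of TPM, median-of-ratios scaling, rescaling without mitochondrial, haemoglobin and ribosomal protein genes, scaling to equal pan-neuronal genes, and the highest row per symbol. The tables held 0 mitochondrial gene rows. After seeing the data, 2 more were added: summing same-strand rows that overlap by at least 80% as 1 locus, and keeping protein-coding genes alone. The scaling to equal pan-neuronal genes shifted the median log2 ratio of all genes from −0.02 to −0.15 in the library labelled Isl1CKO, from 0.02 to −0.23 in Pou4f1KO and from −0.01 to −0.09 in the library labelled DKO. It shifted the median departure from −0.01 to 0.28. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.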

Results

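RNA from the embryonic day 11.5 cochleovestibular ganglion was compared between 4 mouse genotypes, with 1 library each from control, Isl1CKO, Pou4f1KO and DKO embryos. ISL1 is a LIM-homeodomain transcription factor and POU4F1 (BRN3A) a POU-homeodomain transcription factor, and both are made in early sensory neurons. The comparisons addressed how these factors shape the differentiation of inner ear sensory neurons. The aligned sequence came to 16.6 gigabases in control, 13.6 in Isl1CKO, 16.6 in Pou4f1KO and 16.1 in DKO, and a gene at 1 TPM was covered 4.95 to 5.93 times on average. Between 14284 and 14412 genes reached 1 TPM in a library. There were no replicates, so each difference given here has no replicate check, and genes are described as higher or lower in a library.

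The targeted genes were examined first. Pou4f1 (mm10 chromosome 14, 104462325 to 104467999, minus strand, up to 3 exons in GENCODE M21) stood at 146 TPM in control and 188 TPM in Isl1CKO, against 16.6 TPM in Pou4f1KO and 14.6 TPM in DKO. Its log2 ratio to control was −3.06 in Pou4f1KO and −3.23 in DKO, which goes with both labels. Isl1 (chromosome 13, 116298270 to 116309688, minus strand, up to 6 exons) did not go with its labels. It stood at 450 TPM in control, 854 TPM in Isl1CKO, 340 TPM in Pou4f1KO and 579 TPM in DKO, with a log2 ratio to control of 0.92 in Isl1CKO and 0.36 in DKO. A value for the whole gene need not cover the deleted part of a conditional allele, so it does not check the Isl1 labels. These libraries are therefore called the library labelled Isl1CKO and the library labelled DKO. Where the names Isl1CKO, DKO or single mutant stand alone, they refer to these labels.

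**Figure D1:**
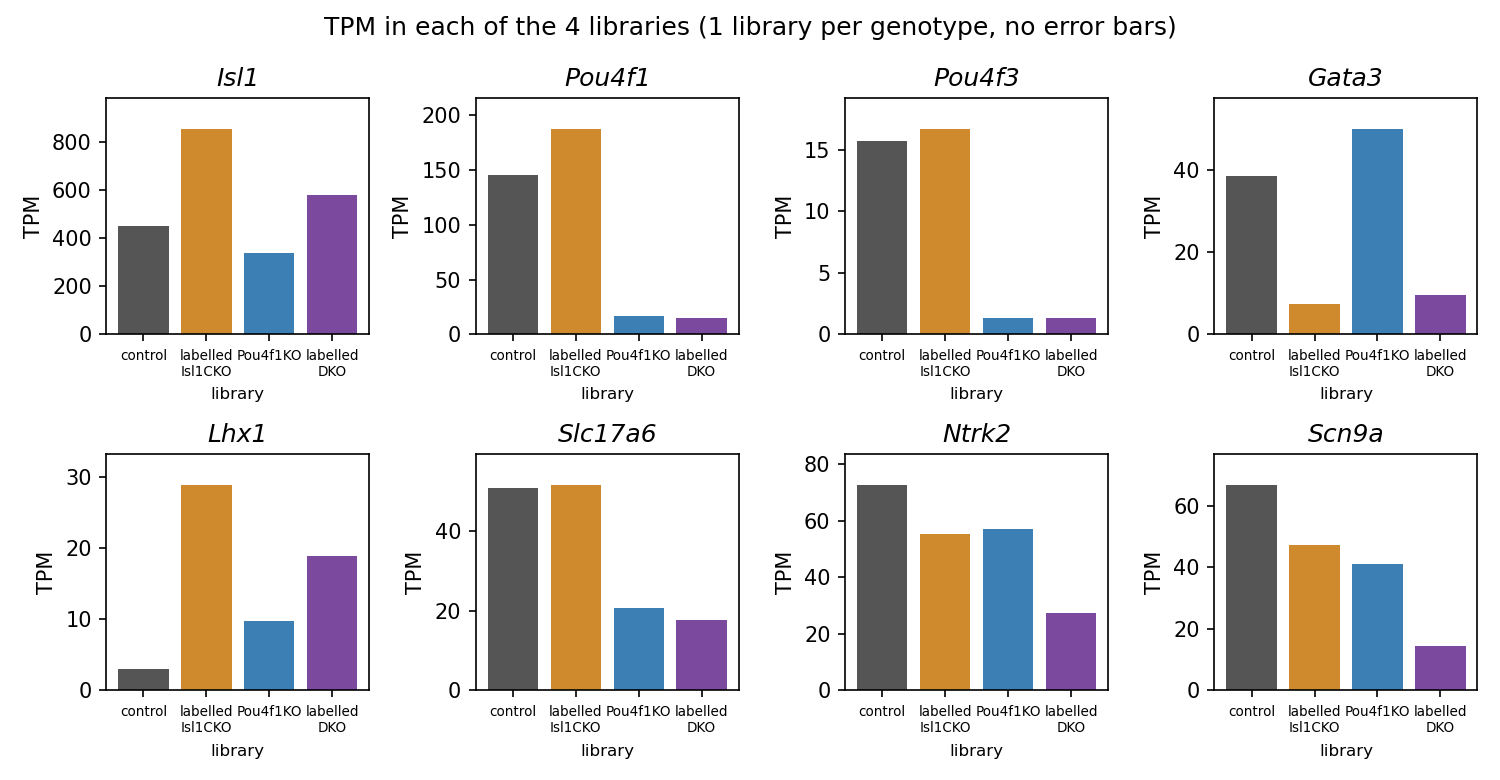
Bars give the TPM of 8 genes in each of the 4 libraries, 1 library per genotype, with the vertical axis in TPM from 0. Pou4f1 and Pou4f3 are low in Pou4f1KO and the library labelled DKO, Gata3 is low in the libraries labelled Isl1CKO and DKO, and Isl1 is higher in the library labelled Isl1CKO (854 TPM) than in control (450 TPM).

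The question for the library labelled Isl1CKO was which genes differ from control where Isl1 is marked as deleted. Gata3, which encodes a zinc-finger factor needed for cochlear neuron development, was at 38.5 TPM in control and 7.39 TPM in this library, a log2 ratio of −2.24. Lhx1, a LIM-homeodomain gene of the neural tube, was at 3.05 and 28.8 TPM (log2 ratio 2.88), and its antisense neighbour Lhx1os was at 3.01 and 26.8 TPM (2.79). The groups whose medians lay lowest were epithelial, mesenchymal and sex-linked, and the glycolysis genes were higher as a group. Because Isl1 itself was higher in this library, every direction here rests on a label that its own gene does not check.

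Among the other lower genes were Gnat3 (log2 ratio −2.54), which encodes the taste G protein subunit gustducin, Chrdl1 (−1.77), a chordin-like BMP antagonist, Zbed6 (−1.60), the kainate receptor gene Grik3 (−1.45), Lnpep (−1.43) and Ptpn4 (−1.38). Cyp26a1, a retinoic acid-degrading enzyme, had a log2 ratio of −1.51. The higher genes included Prdm8 (2.33), the neurexophilin gene Nxph4 (2.10), Bhlhe23 (1.72), the Groucho-type co-repressor genes Tle2 (1.70) and Tle6 (1.67), and the protocadherin gene Pcdh10 (1.59). Actc1, the cardiac alpha-actin and a member of the cartilage and muscle list, whose median was −0.21, was at 53.9 TPM in control and 191 TPM here (1.81), Nexn, an actin-binding protein, had a log2 ratio of 1.92 and Art5 of 1.88. Sln, which encodes sarcolipin, was listed at 0 in control and stood at 5.09 TPM.

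The neuronal lists showed few members past 2-fold in the library labelled Isl1CKO. Of 29 otic neurogenesis factors, 1 was at least 2-fold higher (Neurod4, log2 ratio 1.04), 1 was lower (Gata3) and 27 lay between, with a median of 0.19 at percentile 100 of the matched random lists, or 0.05 under pan-neuronal scaling. Neurod6 had a log2 ratio of 0.61 and Neurog1 of −0.58. None of the 28 pan-neuronal genes reached 2-fold, and their median of 0.06 (percentile 99.5) became −0.08 once libraries were scaled to equal pan-neuronal genes. The largest ratios there were those of Nsg2 (0.81), Rbfox3 (0.56) and Prph (−0.52). Neurotrophic factors and receptors had a median of −0.32 (percentile 0) with 0 of 17 members past 2-fold. The neurotrophin gene Ntf3 had a log2 ratio of −0.68 and Ntrk3, which encodes the neurotrophin receptor TrkC, of −0.67. Axon guidance genes had a median of −0.20 (percentile 0), with Robo3 (−1.07), the midline-crossing receptor, alone among 46 members past 2-fold; Sema3e had a log2 ratio of −0.92. Ion channel and transmitter genes had a median of −0.00, which turned positive under median-of-ratios scaling, with 1 of 52 members lower (Grik3). Neuropeptide genes had a median of 0.03 that turned negative under pan-neuronal scaling, with Cartpt (1.29) the 1 of 18 members past 2-fold. Somatosensory ganglion genes had a median of −0.08 (percentile 16.8), with 1 of 17 lower, the sodium channel gene Scn10a (−1.25).

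Several lists of signalling and cell state stood apart without single genes past 2-fold. Epithelial, mesenchyme and endothelial lists were lower in this library too. The medians of these lists and of the neuronal lists were therefore not separated from tissue content. Glycolysis and hypoxia genes had a median of 0.31 (percentile 100, 22 members), or 0.18 under pan-neuronal scaling, with the lactate transporter gene Slc16a3 at 0.73, Bnip3 at 0.54 and Ldha at 0.52. Proliferation genes had a median of −0.17 (percentile 0, 30 members), with Cenpf at −0.54 and Mki67 at −0.51. Notch genes had a median of −0.19 (percentile 0.07, 18 members), with Hes5 at −0.61. The median of 23 p53 targets was 0.09 (percentile 99.7), with Cdkn1a at 0.61, and it became −0.04 under pan-neuronal scaling. Apoptosis regulators (28 members) had a median of −0.00 and immediate-early genes (22 members) of −0.01, and both turned positive under median-of-ratios scaling.

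Lists of other cell types also differed from control. Otic epithelium markers had a median of −0.54 (percentile 0), with 2 of 26 lower, Gata3 and Fgf10 (−1.03). Surface ectoderm markers had a median of −0.71, mesenchyme markers of −0.48 and endothelial markers of −0.40 (percentiles 0, 0 and 0.01), with Prrx2 (−1.04) the 1 member of these past 2-fold. Cartilage and muscle markers had a median of −0.21 (percentile 1.40), with Actc1 higher against that median. Erythroid (−0.12), macrophage (−0.15) and glial markers (−0.09) had no member past 2-fold. The 33 neural tube factors had 2 members higher, Lhx1 and Lhx2 (1.39), around a median of 0.04 that turned negative under pan-neuronal scaling and when libraries were rescaled without haemoglobin and ribosomal protein genes. The medians of Hox genes (0.03, 11 members) and of visceral and motor neuron factors (0.09, 11 members) turned negative under pan-neuronal scaling, with no member past 2-fold. All 4 measured Y-linked genes were lower, with Kdm5d at −1.74, Uty at −1.44 and Ddx3y at −1.39, and Xist had a log2 ratio of 0.61. Xist and Y-linked genes were both measured in every library, which argues against only female or only male tissue in any of them. These ratios were not separated from the mix of sexes. In all, 88 genes were at least 2-fold higher and 93 lower in the library labelled Isl1CKO. Scaled to equal pan-neuronal genes these counts were 68 and 135, and with FPKM they were 36 and 25.

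The question for Pou4f1KO was which genes differ from control where Pou4f1 is deleted. The otic epithelium list was lower as a group, the Hox and neural tube lists were higher, and single genes of sensory neurons were among the lowest. Pou4f3, the POU-domain paralog known from hair cells and sensory neurons, was at 15.7 TPM in control and 1.29 TPM in Pou4f1KO (log2 ratio −2.86). Pvalb, a calcium-binding protein of sensory neurons, was at 13.7 and 0.535 TPM (−3.26), and Oc90, the main otoconial matrix protein, at 128 and 12.8 TPM (−3.23). Olig3, a dorsal neural tube factor, was at 0.447 and 13.9 TPM (3.36).

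Pappa2, a protease of IGF-binding proteins, had a log2 ratio of −3.01, Plekhd1 of −2.94 and Cyp26c1, a retinoic acid-degrading enzyme, of −2.71. The claudin genes Cldn6 (−2.67), Cldn24 (−2.56) and Cldn4 (−2.40) and the keratin gene Krt8 (−2.43), all of epithelia, were also among the lowest. The highest genes included Hoxd3 (3.26), Sim1 (3.11), Hoxc4 (2.73), Otp (2.63), Atoh1 (2.45), the proneural factor of the rhombic lip and of hair cells, Msx3 (2.32) and Neurog2 (2.20). Short non-coding RNA genes stood among them: Rpph1, the RNA of ribonuclease P, was at 2.40 TPM in control and 45.9 TPM in Pou4f1KO, Rmrp at 4.96 and 38.5 TPM, and Scarna2 had a log2 ratio of 2.69. The ribosomal RNA precursor Rn45s was at 3003 TPM in Pou4f1KO against 655 to 844 TPM in the other libraries. The haemoglobin genes Hbb-bs and Hbb-b1 had log2 ratios of −5.66 and 5.93, but they lie on overlapping rows whose sum had a log2 ratio of 0.02.

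Among neuronal lists, otic neurogenesis factors had 2 members higher (Neurod4, 1.19, and Neurod6, 1.14) and 3 lower in Pou4f1KO. The lower ones were Pou4f3, Runx1 (−1.28), a factor of nociceptive neurons, and Pou4f2 (−1.16). Their median of 0.20 (percentile 100) became −0.05 under pan-neuronal scaling. Pan-neuronal genes had a median of 0.29 (percentile 100), with Nsg2 at 0.79 and Dcx at 0.60 and 0 of 28 past 2-fold. Ion channel and transmitter genes had a median of 0.36 (percentile 100). The higher members were Kcnd2 (1.62), Grik1 (1.28) and Glra2 (1.21). The potassium channel gene Kcna1 (−1.29) and Slc17a6 (−1.26), which encodes the vesicular glutamate transporter VGLUT2, were lower. Neuropeptide genes had a median of 0.30 (percentile 100), with Scg2 (1.83), Tac1 (1.20), which encodes substance P, and Npy (1.01) higher. Somatosensory genes had a median of −0.10 (percentile 6.45) with 4 of 17 lower: Pvalb, Pou4f2, Avil (−1.11) and Scn10a (−1.10). Neurotrophic factors and receptors had a median of 0.03 that turned negative under pan-neuronal scaling, and Ntf3 (−1.26) was lower. Axon guidance genes had a median of 0.14 (percentile 100) that became −0.11 under the same scaling, with Robo3 (1.37), Dcc (1.32) and Sema3c (1.09) higher and Sema3a (−1.04) and Unc5b lower. That scaling also brought the medians of pan-neuronal genes to 0.02, of ion channel genes to 0.11 and of neuropeptide genes to 0.06. Hox and neural tube lists were higher in this library too, so the medians of the neuronal lists were not separated from tissue content.

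Proliferation genes had a median of −0.29 (percentile 0) in Pou4f1KO, with Ccnd1 at −0.65 and Ccne1 at −0.48. Notch genes had a median of 0.05 that turned negative under pan-neuronal scaling, with Hes5 (2.04), a Notch target of neural progenitors, higher and Lfng (−1.04) lower. The p53 targets had a median of −0.01 (percentile 25.3) and no member past 2-fold. Apoptosis regulators had a median of 0.06 that turned negative under pan-neuronal scaling, with Hrk (−1.15), a BH3-only gene, lower. Immediate-early genes had a median of 0.14 (percentile 98.9) that became −0.14 under the same scaling, and glycolysis genes had a median of −0.03 (percentile 25.7).

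The list medians farthest from 0 in Pou4f1KO belonged to markers of other cells. Of 26 otic epithelium markers 17 were lower and 1, Pax8 (1.07), was higher, with a median of −1.19 (percentile 0); Lmx1a had a log2 ratio of −2.37 and Cldn7 of −2.08. Of 10 surface ectoderm markers 8 were lower, with a median of −2.03 (percentile 0), among them Krt18 (−2.22), Krt19 (−2.21) and the epithelial adhesion gene Epcam (−2.06). Of the 11 of 26 Hox genes that reached 1 TPM in some library, 10 were higher, with a median of 1.79 (percentile 100). Hoxd4 (2.14) and Hoxb4 (2.12) were among them. Of the 33 of 48 neural tube factors that did so, 18 were higher and 3 lower, with a median of 1.23 (percentile 100). Skor2 (−2.17), Irx3 (−1.47) and Irx5 (−1.10) were the lower ones. Some members of both lists, such as Hoxd3 (10.1 TPM, against 0.160 TPM in control) and Olig3, passed that filter only through Pou4f1KO. The filter therefore favours higher values in this library. Glial markers had a median of 0.30 (percentile 100) and visceral and motor neuron factors of 0.22 (percentile 98.5), with Tbx2 (−1.46) lower, and these medians were 0.04 and 0.03 under pan-neuronal scaling. Mesenchyme (−0.17), endothelial (−0.12), erythroid (−0.24) and macrophage markers (−0.30) had medians below 0, with the mesenchymal gene Six2 (−1.61) lower, and cartilage and muscle markers had a median of −0.03 with Cnmd (−2.21), Col9a1 (−1.22) and Matn1 (−1.10) lower. The median of 5 sex-linked genes was −0.03 (percentile 31.5). In all, 147 genes were higher and 260 lower, of which 30 and 32 belonged to lists of other cell types. The lists are not exhaustive, as Cldn24 stands on none of them, so these are no full counts of genes of other cells. Scaled to equal pan-neuronal genes, 103 were higher and 394 lower, and with FPKM 71 and 138.

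**Figure D2:**
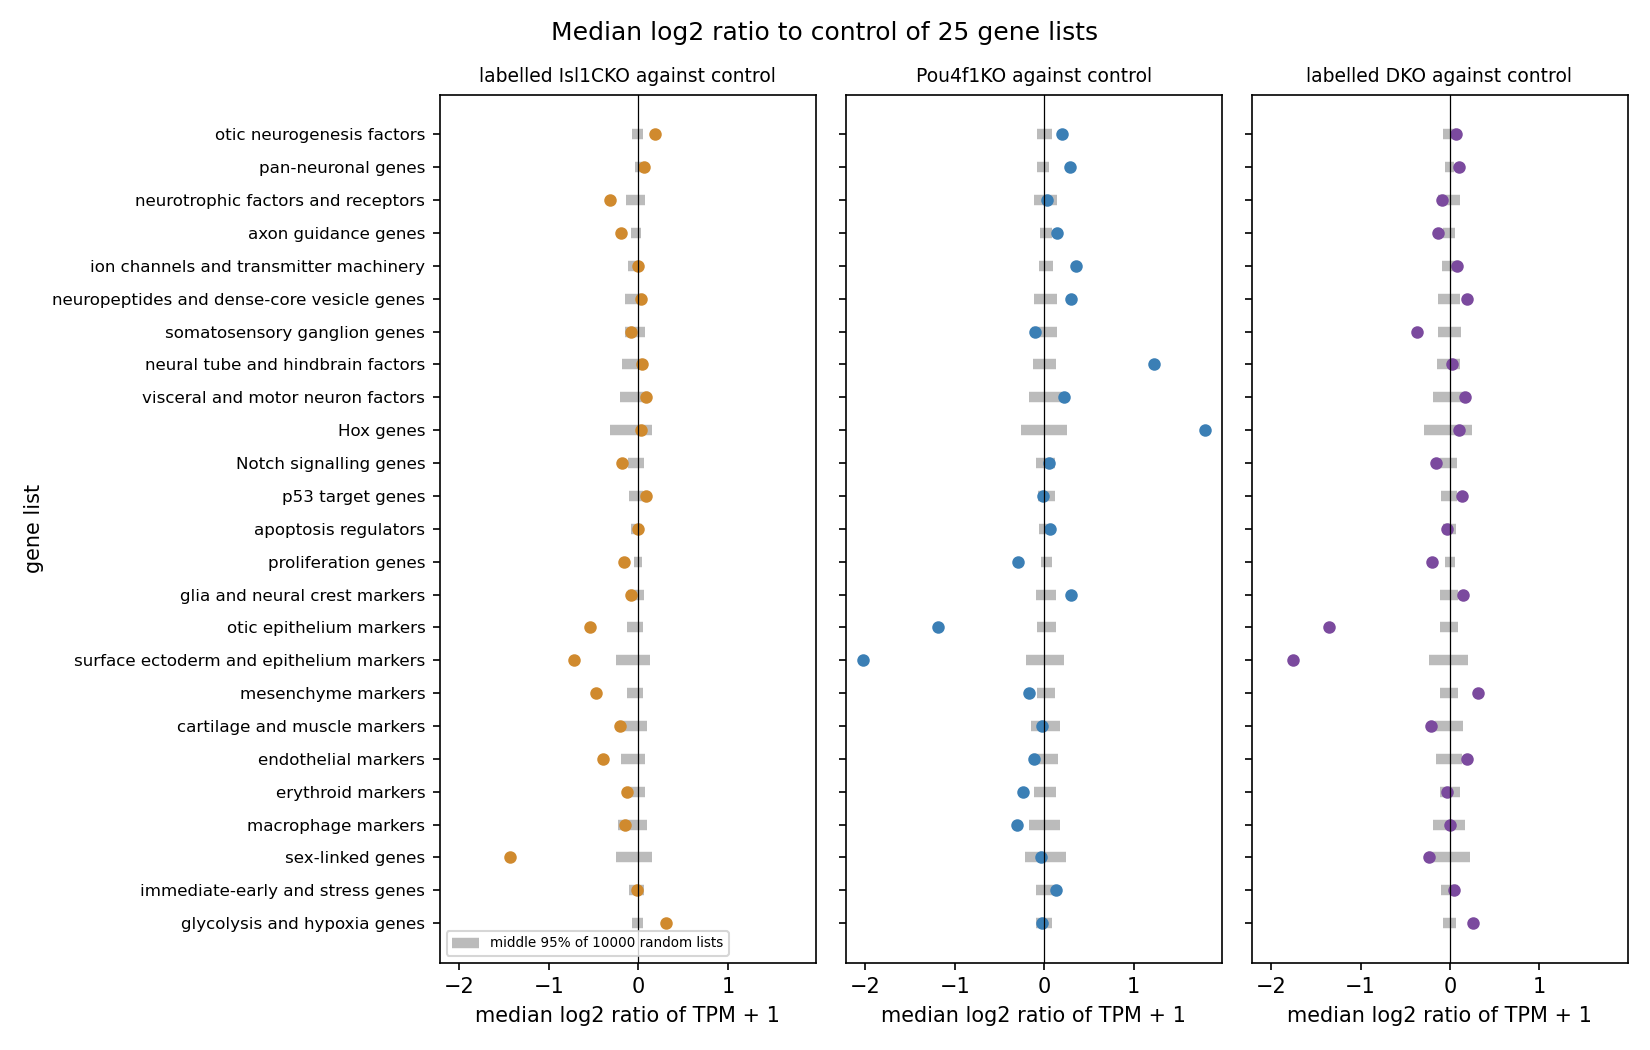
Points give the median log2 ratio of (TPM + 1) to control for each gene list in the library labelled Isl1CKO, in Pou4f1KO and in the library labelled DKO, and grey bars span the middle 95% of the medians of 10000 matched random lists. In Pou4f1KO the Hox list stands at 1.79 and the surface ectoderm list at −2.03, and neither changed direction under any scaling, whereas small medians such as those of the otic neurogenesis (0.20) and axon guidance (0.14) lists in Pou4f1KO turned negative under pan-neuronal scaling.

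The question for the library labelled DKO was how the transcriptome differs from control where both genes are marked as deleted. Otic epithelium markers were lower as a group, and single genes of neuronal excitability were lower while their list was not. Scn9a, the sodium channel NaV1.7, was at 66.8 TPM in control and 14.6 TPM in this library (log2 ratio −2.12), and Ppp1r1c, a protein phosphatase 1 inhibitor, was at 100 and 8.42 TPM (−3.43). Hmx3, a homeobox gene of the otic vesicle, was at 13.4 and 0.593 TPM (−3.18). Ttr, the thyroid hormone carrier transthyretin, was the highest, at 2.36 TPM in control and 44.8 TPM here (3.77). Isl1 was also above control in this library (579 against 450 TPM), so the directions rest on a label that this gene does not check, whereas Pou4f1 was at 14.6 TPM.

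Further lower genes were Plekhd1 (log2 ratio −3.05), Pou4f3 (−2.86), Pappa2 (−2.82), Otol1 (−2.81), which encodes the inner ear collagen otolin, Prr15 (−2.74), the secreted-protein gene Tafa2 (−2.65), Epcam (−2.59) and Gnat3 (−2.59). Further higher genes were the cadherin gene Cdh9 (2.65), Sim1 (2.62), Prdm8 (2.53), Nxph4 (2.48), the channel gene Pkd2l1 (2.30), Lhx1 (2.30), Lmo3 (2.26), Nexn (2.25), Lhx1os (2.24) and Scg2 (2.14). Sln was listed at 0 in control and stood at 8.06 TPM. Rpl26, a ribosomal protein gene, had a log2 ratio of −4.50, but its row overlaps that of Gm15772, and the sum of both had a log2 ratio of −0.04.

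Of 17 somatosensory genes 6 were lower and 1 higher (Cbfa2t3, 1.11) in the library labelled DKO, with a median of −0.37 (percentile 0); Prrxl1, a homeobox gene of sensory neurons also known as Drg11, had a log2 ratio of −2.02 and Pou4f2 of −1.91. Of 29 otic neurogenesis factors 6 were lower, among them Gata3 (−1.92) and Runx1 (−1.78), and Neurod6 (1.42) was higher; their median of 0.07 turned negative under pan-neuronal scaling. Ntrk2 (−1.37), which encodes the BDNF receptor TrkB, and Ntf3 (−1.32) were the 2 of 17 neurotrophic genes past 2-fold, with Ntrk3 at −0.96 and a median of −0.09 (percentile 7.75). Of 46 axon guidance genes 6 were lower, among them Sema3e (−1.82), Epha5 (−1.61) and Cntn2 (−1.55), with a median of −0.13 (percentile 0.03). Of 52 ion channel and transmitter genes 5 were lower, among them Kcna1 (−1.75) and Slc17a6 (−1.47), and 2 higher, Kcnd2 (1.43) and Glra2 (1.40), with a median of 0.08 (percentile 99.1). Prph (−1.39), an intermediate filament gene of peripheral neurons, was the 1 pan-neuronal gene past 2-fold, with a median of 0.10 (percentile 100). Scg2, Penk (1.51), which encodes proenkephalin, Cartpt (1.37) and Npy (1.17) were higher among neuropeptide genes, Pcsk2 (−1.11) was lower, and the median was 0.19 (percentile 99.9). Under pan-neuronal scaling the medians of ion channel, pan-neuronal and neuropeptide genes were 0.00, 0.02 and 0.10.

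Proliferation genes had a median of −0.20 (percentile 0) and Notch genes of −0.16 (percentile 0.29, with Lfng at −1.36). Glycolysis genes had a median of 0.26 (percentile 100) and p53 targets of 0.13 (percentile 99.8), with Cdkn1a at 0.66 and a p53 median of 0.05 under pan-neuronal scaling. Apoptosis regulators had a median of −0.03 (percentile 24.3) with Hrk (−1.15) lower, and immediate-early genes had a median of 0.05 that turned negative under pan-neuronal scaling. Epithelial lists were lower and the mesenchyme list higher in this library. The medians of the cell state and neuronal lists were therefore not separated from tissue content.

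Of 26 otic epithelium markers 15 were lower and 1, Tbx1 (1.46), higher in the library labelled DKO, with a median of −1.35 (percentile 0); Cldn6 had a log2 ratio of −2.43. Of 10 surface ectoderm markers 8 were lower, with a median of −1.75 (percentile 0), among them Cldn4 (−2.39) and Esrp1 (−2.21). Mesenchyme markers had a median of 0.32 (percentile 100), with Tbx18 (1.28) higher and Six2 (−1.62) lower, and endothelial markers of 0.19 (percentile 99.6), or 0.12 under pan-neuronal scaling. Glial markers had a median of 0.15, or 0.06 under that scaling, and visceral and motor neuron factors of 0.16, with Tbx2 (−2.28) lower. Hox genes had a median of 0.10 with 0 of 11 past 2-fold. The 33 neural tube factors had 4 higher, among them Sim1, Lhx1, Lhx2 (1.86) and Nkx6-1 (1.68), and 3 lower; their median of 0.02 turned negative under pan-neuronal scaling. Cartilage and muscle markers had a median of −0.22 with Actc1 (1.91) higher and Cnmd (−1.47) lower. Erythroid markers had a median of −0.04 (percentile 27.0), macrophage markers of 0.00 that turned negative under pan-neuronal scaling, and sex-linked genes of −0.24 (percentile 2.60). In all, 152 genes were higher and 352 lower than in control, or 75 and 186 with FPKM and 51 and 127 with a pseudocount of 5.

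The library labelled DKO was next set against each single mutant, to see what the second label adds. Against the library labelled Isl1CKO, several genes lower in Pou4f1KO than in control were lower too. Pou4f1 had a log2 ratio of −3.60, Pou4f3 of −2.94, Ppp1r1c of −2.93, Plekhd1 of −2.83 and Pappa2 of −2.75, while Sim1 (2.43), Ttr (2.36), Penk (1.87), Cyp26a1 (1.85), Scg2 (1.75) and the glutamate receptor gene Grin3a (1.72) were higher. Surface ectoderm and otic epithelium markers had medians of −0.99 and −0.79, and Slc17a6 had a log2 ratio of −1.48. Mesenchyme and endothelial markers had medians of 0.73 and 0.60, with 7 of 25 mesenchyme markers higher, among them Twist2 (1.54), and the 4 Y-linked genes were higher, with Eif2s3y at 1.49. In all, 131 genes were higher and 185 lower, or 32 and 101 with FPKM. Proliferation genes had a median of −0.04 that became 0.01 under pan-neuronal scaling, and somatosensory genes had a median of −0.17 that became 0.01 with a filter of 5 TPM. The Isl1 label is common to both libraries here but is unchecked in each. Isl1 stood at 854 TPM in the library labelled Isl1CKO and 579 TPM in the library labelled DKO (log2 ratio −0.56). A difference in Isl1 status between them was therefore not excluded.

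Against Pou4f1KO, the library labelled DKO had lower Olig3 (log2 ratio −3.27), Insm2 (−3.26), a zinc-finger gene of neuroendocrine cells, Rpph1 (−3.23), Hoxd3 (−3.14), Robo3 (−2.73) and Gata3 (−2.29). Higher genes were Sln (8.06 against 0.0913 TPM), Cyp26c1 (2.79), Prdm8 (2.49), Ttr (2.31) and Cyp26a1 (2.04). Hox genes had a median of −1.78 with 9 of 11 lower and neural tube factors of −0.99 with 16 of 33 lower. Some of these members, such as Hoxd3 and Olig3, reached 1 TPM only in Pou4f1KO, so the filter favours this direction. The medians of the neuronal lists that follow were not separated from tissue content in Pou4f1KO. Pan-neuronal (−0.20), axon guidance (−0.28), ion channel (−0.24) and Notch genes (−0.23) had medians below 0, which were −0.02, −0.11, −0.06 and −0.05 under pan-neuronal scaling, and glycolysis (0.26), mesenchyme (0.47), endothelial (0.35) and macrophage markers (0.36) above 0. The median of neurotrophic genes was −0.17 and became 0.00 under pan-neuronal scaling; that of immediate-early genes was −0.12 and became 0.08. In all, 97 genes were higher and 168 lower, or 126 and 123 after that scaling and 42 and 69 with FPKM, and each direction rests on the unchecked Isl1 label.

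Whether each label went with the same differences in both backgrounds was asked with pairs that share no library. For Isl1, the library labelled Isl1CKO against control and the library labelled DKO against Pou4f1KO shared 27 higher and 32 lower genes, where independent lists of these sizes would share 0.567 and 1.04. With FPKM they shared 16 and 9, and with a pseudocount of 5 they shared 10 and 7. Gata3, Gnat3, Chrdl1, Grik3, Robo3, Fgf10, Insm2 and Zbed6 were lower in both, and Prdm8, Sln, Tle2, Tle6, Bhlhe23, Nexn, Actc1, Art5 and Pcdh10 were higher in both. Genes that were at least 2-fold higher in one pair and lower in the other numbered 8. Across 15049 genes, which are not independent replicates, Pearson's r was 0.25 and Spearman's rho 0.19. Isl1 itself was higher in both pairs, with log2 ratios of 0.92 and 0.77, and as before this checks neither label.

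For Pou4f1, Pou4f1KO against control and the library labelled DKO against the library labelled Isl1CKO shared 30 higher and 107 lower genes, where 1.28 and 3.20 would be shared by independent lists. The shared numbers were 8 and 63 with FPKM and 6 and 34 with a pseudocount of 5. Pou4f3, Pvalb, Runx1, Avil, Slc17a6, Kcna1 and Hrk were lower in both, with Epcam, Cldn6, Krt8 and Oc90 beside them. Sim1, Nkx6-1, Scg2, Npy, Kcnd2, Grik1 and Glra2 were higher in both, while Hoxd3 and Olig3 were higher in the first pair alone. Again 8 genes were opposite, Pearson's r across genes was 0.42 and Spearman's rho 0.30. Epithelial markers were lower in both pairs, with surface ectoderm medians of −2.03 and −0.99. Among the shared genes of either direction, 18 belonged to lists of other cell types, and the higher ones held the short non-coding RNAs Rpph1, Rmrp and Scarna2. Cldn24 and Otol1 were lower in both pairs and stand on none of these lists, so 18 is no full count of genes of other cells. Genes that vary together with tissue content would also be shared. For either label, independent lists are therefore no baseline for an effect of the gene's loss.

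**Figure D3:**
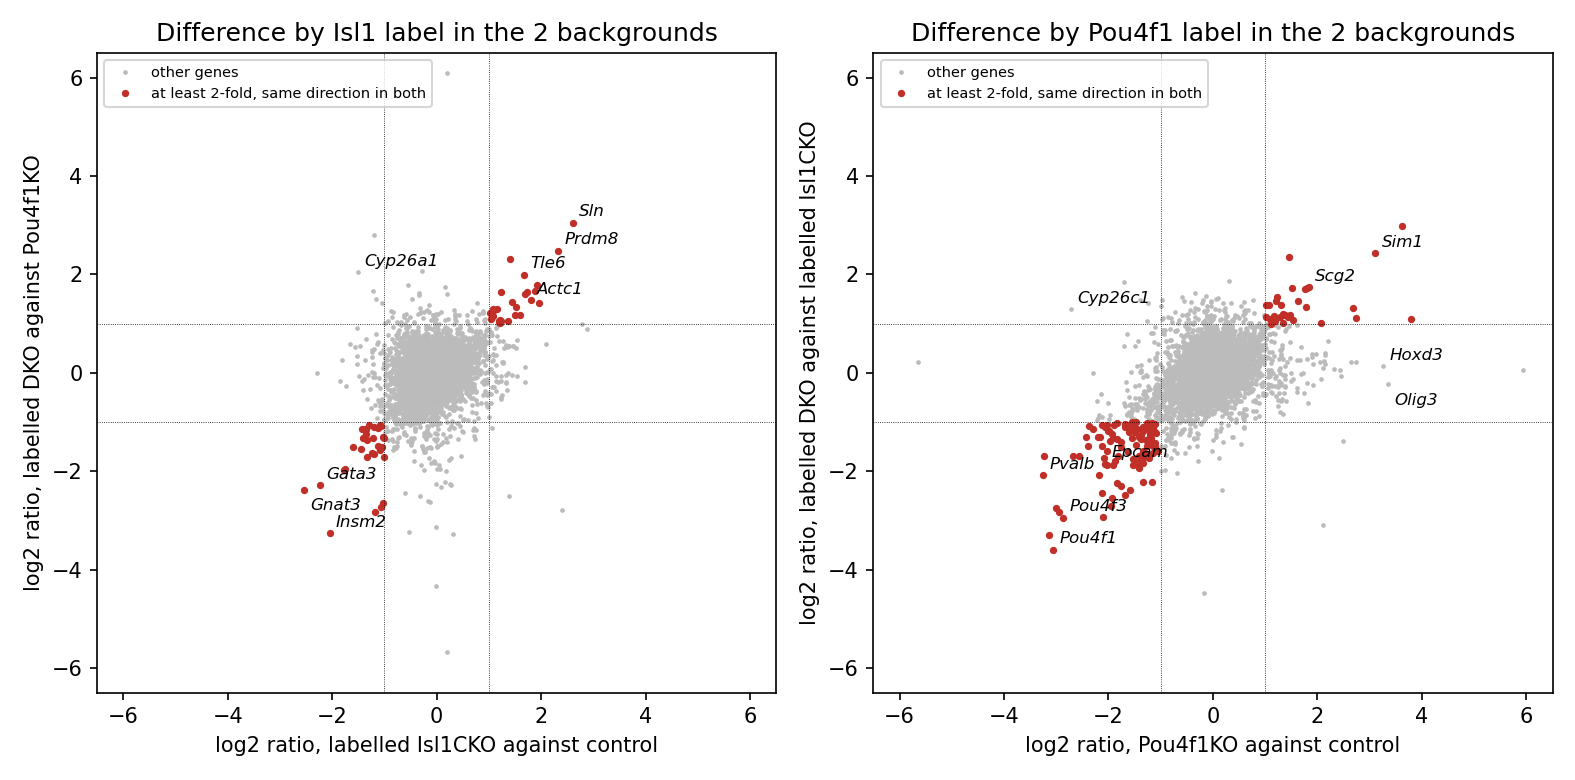
Each point is 1 of 15049 genes, with the log2 ratio of (TPM + 1) in one background on the horizontal axis and in the other on the vertical axis, on the left for the Isl1 label and on the right for the Pou4f1 label; dotted lines mark 2-fold. Red points are at least 2-fold in the same direction in both, 27 higher and 32 lower on the left and 30 higher and 107 lower on the right.

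Genes that differed in both single mutants numbered 20 higher and 24 lower. Lhx1, Lhx2 (1.39 and 1.31), Nxph4, Neurod4 and Ttr were among the higher, and Otol1, Scn10a, Cyp26a1 and Cyp26c1 among the lower. Because both ratios use the same control library, simulated libraries with no true difference gave 16.2 and 26.7 such genes. The simulated spread was taken from the difference between the library labelled Isl1CKO and control, so true differences count in it as noise. The simulated Pearson's r of 0.50 between both ratios follows from a shared control and equal spreads, whatever their size. It is therefore no yardstick for the observed 0.38. The observed numbers are close to the simulated ones, but so wide a spread cannot decide whether the single mutants share differences beyond the shared control. Under pan-neuronal scaling the numbers were 12 higher and 48 lower, and no simulation was run for that scaling.

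The last question was where the library labelled DKO lies beyond both single mutants. It was at least 2-fold above control and both single mutants for 15 genes and below all 3 for 17, or 4 and 7 with FPKM. These counts hold Gm15772 and Rpl26, whose summed rows had a log2 ratio of −0.04 to control, and Rnaset2a, whose sum with its paralog Rnaset2b had one of −0.26. With overlapping rows summed the counts were 12 and 17. The lower set held Scn9a, Ppp1r1c, Tafa2, Otol1, Hmx3 and Prrxl1, and the higher set Ttr, Penk, Lmo3 and Tbx1. Against control, the library labelled Isl1CKO and Pou4f1KO, mesenchyme markers had medians of 0.32, 0.73 and 0.47 in the library labelled DKO. Otic epithelium markers, which include Hmx3 and Tbx1, had medians of −1.35, −0.79 and 0.18. Both sets were therefore not separated from tissue content. Scn9a stood at 66.8, 47.3, 41.0 and 14.6 TPM in control, Isl1CKO, Pou4f1KO and DKO, and Ntrk2, which did not meet this rule, at 72.6, 55.2, 57.2 and 27.5 TPM. Chosen after its values were seen, the thyroid hormone-inactivating enzyme gene Dio3 was at 18.5 TPM in control and 3.46 TPM in the library labelled DKO.

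The departure from the sum of the single-mutant log2 ratios was at least 1 in size for 379 genes, 212 above and 167 below. Under pan-neuronal scaling 440 were above and 120 below, and with FPKM 82 and 65. The lowest departures were those of Olig3 (−3.58), Hoxd3 (−3.13), Rpph1 (−2.69), Atoh1 (−2.52) and Hoxc4 (−2.51), all at least 2-fold higher in Pou4f1KO. Rnaset2a also ranked low (−2.56), but its sum with Rnaset2b, a paralog elsewhere on chromosome 17, had a departure of 0.25. The highest were Cyp26c1 (4.00), Cyp26a1 (3.55), the mesenchymal homeobox gene Prrx2 (2.46), Twist2 (2.13), S100a9 (1.93) and Snai1 (1.79). Cpt1b stood at 2.66, but its sum with the overlapping row of Gm44502 had a departure of −0.87. Haemoglobin and Rpl26 rows also ranked here, and after summing overlapping rows their departures were 0.20 and 0.15. The 28 pan-neuronal genes had a median departure of −0.31, which became 0.01 when libraries were scaled to equal these genes, and the 30 proliferation genes one of 0.23. Pou4f1KO, with its higher Hox and neural tube lists, enters every departure, so these medians were not separated from tissue content. Among lists the largest median departures were those of Hox genes (−1.96, or −0.27 with no filter on low values and −1.12 with FPKM), sex-linked genes (1.27), mesenchyme (0.95), surface ectoderm (0.86) and endothelial markers (0.77) and neural tube factors (−0.84). With 4 libraries for 4 corners, the departure has no residual degrees of freedom and was not tested.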

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

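All of the tests in this part were chosen after the results were seen.

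Of 15049 genes, 10 were at least 2-fold higher in one pair of libraries and lower in the other for at least one of the 2 labels, and 4 of these had been named by the rule. Cyp26a1 and Cyp26c1, neighbouring retinoic acid-degrading enzymes on chromosome 19, went opposite ways: each was lower in both single mutants than in control and higher in the library labelled DKO than in either single mutant. Cyp26a1 stood at 16.3, 5.07 and 4.33 TPM in control, Isl1CKO and Pou4f1KO and had a log2 ratio of 0.35 in the library labelled DKO, a departure from additivity of 3.55. Cyp26c1 stood at 19.7, 7.95, 2.16 and 20.8 TPM in control, Isl1CKO, Pou4f1KO and DKO, a departure of 4.00. Prrx2, a mesenchymal homeobox gene, stood at 12.8, 5.71, 6.01 and 17.7 TPM, a departure of 2.46. Cpt1b, a fatty acid import enzyme, stood at 4.98, 1.68, 1.53 and 6.16 TPM, a departure of 2.66, but its row overlaps that of Gm44502, and their sum stood at 5.60, 9.23, 7.46 and 6.16 TPM, a departure of −0.87. The mesenchyme list, which holds Prrx2, had medians of −0.48, −0.17 and 0.32 against control in Isl1CKO, Pou4f1KO and DKO and a median departure of 0.95 with 24 of 25 members above 0, and endothelial markers had one of 0.77, so these genes were not separated from tissue content. With 1 library per genotype these differences between backgrounds were not tested.

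Epithelial and otic epithelial markers were lower in Pou4f1KO and in the library labelled DKO. Scaling of the libraries is argued against, since the higher of both list medians in Pou4f1KO reached no more than −1.20 under any other scaling. Less otic epithelium in the dissected tissue and lower output of these genes within the epithelium, tied to Pou4f1, cannot be told apart, because no measure of tissue amount was analysed here. The median of −2.03 over the surface ectoderm list in Pou4f1KO does not decide between them, since that list is part of the pattern. The library labelled Isl1CKO, with its higher Pou4f1, also had a median of −0.71 for that list, so these markers did not track Pou4f1 alone.

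Hox genes and neural tube factors were higher in Pou4f1KO, with 28 members of both lists past 2-fold and a median over these of 1.76. An effect of Pou4f1 loss whatever the Isl1 label is argued against: the median of these 28 in the library labelled DKO against the library labelled Isl1CKO was 0.05 (0.0497), although Pou4f1 was as low there. These 28 were picked for being high in Pou4f1KO, so smaller values elsewhere are partly fixed by that choice. Over all measured members, the medians of the same comparison were 0.11 for Hox genes and −0.03 for neural tube factors. A piece of neural tube in the Pou4f1KO dissection is a candidate explanation, and 14.3% of the members (4 of 28) were past 2-fold in the library labelled DKO as well. An effect of Pou4f1 loss confined to the background not labelled for Isl1 cannot be told apart from such tissue, since the median in the library labelled DKO against control was 0.15 and each genotype has 1 library. The 4 shared members, Lhx1, Lhx2, Nkx6-1 and Sim1, are not accounted for by tissue in Pou4f1KO alone.

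Some gene rows differed by over 16-fold between single libraries. Rpl26 was at 812 TPM in control and 34.9 TPM in the library labelled DKO, while the overlapping Gm15772 was at 725 and 1462 TPM. A division of the same reads between overlapping rows may account for this, as the summed rows had a log2 ratio of −0.0386, and that value argues against a lower output of the Rpl26 locus. For Hbb-bs and Hbb-b1 in Pou4f1KO, the summed rows had a log2 ratio of 0.0209.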

How the results depend on the processing

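The settings that sum overlapping rows or keep protein-coding genes were chosen after the results were seen; all others were planned. No paired analysis was possible because each genotype had 1 library, and for the same reason no library could be left out. A count or correlation was taken as the same within 1.5 times its value, and a log2 ratio within log2 of 1.5, since no replicate spread exists. The coverage of 4.95 to 5.93 at 1 TPM limits the precision of genes near that level, and the counts depend on them. Pearson's r and Spearman's rho between backgrounds stayed within that range under every setting.

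Counts of genes past 2-fold depended on how low values were treated, which follows from the construction of the log2 ratio. With a pseudocount of 0.1 the higher and lower counts were 220 and 287 for the library labelled Isl1CKO against control, 323 and 469 for Pou4f1KO, and 343 and 605 for the library labelled DKO. For the library labelled DKO they were 343 and 387 against Isl1CKO and 247 and 369 against Pou4f1KO, and the departure had 505 above and 358 below. Both single mutants shared 88 higher and 98 lower genes, both pairs for Isl1 shared 70 and 89, and both pairs for Pou4f1 shared 87 and 201. Opposite genes numbered 74 for Isl1, 68 for Pou4f1 and 100 for either, and the library labelled DKO lay above all 3 others for 51 genes and below for 80. With a pseudocount of 5, in the same order, the counts were 22 and 14, 31 and 87, 51 and 127, 16 and 55, 24 and 41, 39 and 27, 3 and 2, 10 and 7, and 6 and 34, then 2, 1 and 2 opposite, and 4 above and 4 below. FPKM, whose values are smaller so that adding 1 weighs more, gave 36 and 25, 71 and 138, 75 and 186, 32 and 101, 42 and 69, 82 and 65, 8 and 5, 16 and 9, and 8 and 63, then 3, 3 and 3 opposite, and 4 above and 7 below. The balance of higher and lower genes in the library labelled Isl1CKO, 88 to 93, therefore tipped to 22 to 14 and 36 to 25 in these settings.

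With a filter of 5 TPM, which leaves fewer genes, the counts were 52 and 51 for Isl1CKO, 88 and 167 for Pou4f1KO, 93 higher for DKO, 76 higher for DKO against Isl1CKO, 51 and 97 for DKO against Pou4f1KO, 102 above and 69 below for the departure, and 12 and 9 shared by both single mutants. Opposite genes then numbered 5 for Isl1, 4 for Pou4f1 and 5 for either, and 6 genes in the library labelled DKO lay above all 3 others. Protein-coding genes alone gave 45 higher for Isl1CKO, 60 higher for DKO against Pou4f1KO, 87 below for the departure, and 11 and 15 shared by both single mutants. Opposite genes numbered 5 for Pou4f1 and 6 for either, and 9 lay above and 11 below all 3 others.

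Scaling to equal pan-neuronal genes, which divides Pou4f1KO by 1.11 and control by 0.926, gave 394 lower genes in Pou4f1KO, 440 above additivity, 12 higher and 48 lower in both single mutants, and 10 below all 3 others in the library labelled DKO. It turned the median of the otic neurogenesis (−0.0491), axon guidance (−0.11) and immediate-early lists (−0.14) in Pou4f1KO and of the p53 list (−0.0431) in the library labelled Isl1CKO. For the library labelled DKO it turned the neurotrophic (0.00, or 0.0039) and immediate-early lists (0.0795) against Pou4f1KO and the proliferation list (0.0070) against Isl1CKO. The pan-neuronal list became −0.0768 in the library labelled Isl1CKO and 0.01 (0.0056) in the departure, which its own scaling fixes near 0. A filter of 5 TPM turned the somatosensory list against Isl1CKO (0.0070) and the immediate-early list in Pou4f1KO (−0.0375); the cause was not tested.

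Summing overlapping rows turned Hbb-bs in Pou4f1KO (0.0209), Hbb-b1 (0.41) and Rpl26 (0.14) in the library labelled DKO against Pou4f1KO, and the departures of Hbb-b1 (0.20) and Rpl26 (0.15). No other value of a named gene past 2-fold turned. For ratios between libraries this follows from the construction of the other settings, apart from the highest row per symbol, and is no measure of stability. Those settings shift all genes alike by less than 2-fold or keep the sign of a ratio. A departure could have turned with another pseudocount or with FPKM, and none of the named ones did. Of 133 list medians 123 had no turn, counting a turn only where the median lay outside the middle 95% of random lists. Counted at any size, 30 of 133 turned under pan-neuronal scaling, the largest from a size of 0.31. Rescaling without haemoglobin and ribosomal protein genes gave no value for those genes. No count tested here moved past 1.5 times under median-of-ratios scaling, this rescaling, the highest row per symbol, no filter on low values, or summed rows. List medians that moved by more than log2 of 1.5 without a turn numbered 4 of 133 with no filter on low values. They numbered 4 with a pseudocount of 0.1, 5 with a pseudocount of 5 and 3 with FPKM.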

Other observations

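The values in this part were chosen after the results were seen, and no test was planned for them.

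Some muscle-associated genes, picked after their values were seen, were higher in the libraries labelled Isl1CKO and DKO, whereas the cartilage and muscle list had medians of −0.21 and −0.22 there. Actc1 was at 53.9, 191, 73.1 and 206 TPM in control, Isl1CKO, Pou4f1KO and DKO, Nexn at 5.58, 23.9, 8.06 and 30.3 TPM, and the embryonic myosin gene Myh3 at 1.08, 2.48, 1.14 and 2.74 TPM. On the scale of (TPM + 1), Myh3 stayed short of 2-fold. Also higher in both Isl1-labelled pairs, the sarcoplasmic calcium pump gene Atp2a1 was at 11.9, 29.1, 16.1 and 33.5 TPM and the acetylcholine receptor subunit gene Chrng at 10.1, 24.3, 13.2 and 28.1 TPM. The myogenic factor gene Myod1 stayed below 1 TPM in each library, with 0.163, 0.555, 0.0741 and 0.807 TPM, and Myog was at 0.899, 0.445, 0.778 and 0.708 TPM. Lower in both of these pairs were Fzd5, at 3.28, 0.837, 4.96 and 1.39 TPM, and Msc, a bHLH gene also called musculin, at 84.5, 33.1, 160 and 62.1 TPM. The gene-level value of Isl1 does not check the label behind these directions.

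Genes of Y-linked and X-inactivation function differed in 1 library. In the library labelled Isl1CKO, Eif2s3y was at 11.6 TPM against 34.5 to 36.3 TPM in the other libraries, and Xist was at 195 TPM against 127 to 138 TPM. Both kinds of transcript were present in all 4 libraries, which argues against only female or only male tissue in any of them. The sexes of the embryos in each library are not given in the sources used here, so these values are not read as an effect of genotype.

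Ribosomal RNA and several short non-coding RNAs differed in Pou4f1KO. The 45S ribosomal RNA precursor Rn45s was at 674, 655, 3003 and 844 TPM, Rpph1 at 2.40, 1.34, 45.9 and 3.99 TPM, and Rmrp at 4.96, 1.92, 38.5 and 5.35 TPM in control, Isl1CKO, Pou4f1KO and DKO. In the same order Scarna2 was at 0.777, 0.514, 10.4 and 2.77 TPM.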
